A study of Homo sapiens with 8 samples.

How the data were processed

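RNA from COLO829 melanoma cells was biotin-labelled and hybridised to Affymetrix Human Gene 1.0 ST arrays, 1 per sample, for 8 samples in 4 groups of 2: scrambled hairpin with DMSO, scrambled hairpin with PLX4032, MITF hairpin with DMSO, and MITF hairpin with PLX4032. The labels give the hairpin, the treatment and a letter, A or B, for each sample. They do not say whether the 2 samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical. They name a hairpin against MITF and no second one, so no change on knockdown could be set against that of another hairpin. The deposited values are log2 intensities per probe set, and RMA (background correction, quantile normalization and a summary of probes on the log2 scale) is the tool named in the submitters' processing notes, with no version. The genome build and the probe set annotation the authors used are not given in the sources used here, and no coordinates are printed. RMA sets the distribution of all arrays alike, so a shift of most genes in one direction would be removed, and it compresses changes of dim and of very bright probe sets. Scanner intensities were not used here. Values ran from 2.1 to 13.53 with no missing value, and 0 columns belonged to other samples.

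Of 32321 probe sets, 19158 carried exactly 1 gene symbol in the platform annotation (2016), 1388 carried several and 11775 were not listed there or had no symbol. Of the 19158, 19128 matched a current gene record by Entrez identifier (RefSeq names on GRCh38.p14) and 0 symbols changed. The 637 genes with several probe sets were represented by the one with the highest mean over all arrays, which left 18404 genes and no filter on dim genes. For some genes the probe sets disagreed: in the comparison of both perturbations with untreated cells, 18 genes had probe sets called in both directions. HLA-DMA was such a gene on knockdown in DMSO and under PLX4032 in scrambled cells. Probes of families with near-identical members can read more than one gene. No detection calls were used, so signal over background is unknown and a low level is not evidence of absence.

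The fit was limma's lmFit and eBayes (limma 3.58.1, R 4.3.3) with a mean per group over all 8 arrays, 4 residual degrees of freedom and 6.73 prior degrees of freedom. The 6 contrasts were knockdown in DMSO, PLX4032 in scrambled cells, PLX4032 in knockdown cells, knockdown in PLX4032, both perturbations against scrambled DMSO cells, and the interaction. Tests were two-sided, with Benjamini-Hochberg adjustment over 18404 genes within a contrast and a threshold of 0.05. The 25 gene lists held 492 entries, of which 446 were measured; some genes stand in more than one list, such as CXCL8, NGFR and PPARGC1A. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 25 lists within a contrast. No list call held in any contrast when the correlation was estimated from the data, the lowest adjusted p being 0.123, so each call is printed with that adjusted p. The estimate, and the test built on it, had only the 4 residual degrees of freedom to draw on, which leaves little power. The mitosis list was not called even on knockdown in DMSO, where every member fell. A call lost in this way is undecided, and its loss alone does not argue against a list. Fry, which tests whether the genes of a list move one way on balance and compares them with no other genes, kept 17 of 17 calls for knockdown in DMSO, 12 of 12 for PLX4032 in scrambled cells, 10 of 12 for PLX4032 in knockdown cells, 14 of 14 for knockdown in PLX4032, 14 of 14 for both perturbations and 3 of 8 for the interaction. Markers of leukocytes, fibroblasts and keratinocytes were among the lists, as were p53 targets, other cell cycle inhibitors, the BCL2 family, and integrated and ER stress.

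Groups, tests of genes and lists, gene lists and alternatives, except the split of the control arrays, were chosen before the data were examined. The tests of patterns in the closing section were written later, some of them after the values they measure had been seen. The genes named are, per contrast, MITF, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap (not asked for the interaction), up to 4 members with the largest called change in each list described (up to 2 where none passed, and up to 2 for the interaction, a limit set later, with the values in hand), DUSP6, SPRY4 and CCND1 for PLX4032 contrasts, TYR, MLANA and TRPM1 for knockdown contrasts, and PPARGC1A throughout. For TRPM1, MET and UBD the PLX4032 changes behind the interaction are given too. The interaction genes listed in the closing section were limited, after the results were seen, to the largest ones, those always given and members of lists called in the interaction. An interaction was counted as having little room, also by a rule set after the results were seen, where a gene fell past the threshold in 1 arm, and in the other fell less, did not rise past the threshold and began below the median gene of the group (6.766 in scrambled and 6.755 in knockdown DMSO cells). Agreement between contrasts was described by correlations across genes and by overlaps set against independent lists, with 100 simulated draws where control arrays were shared. Alternatives were the letter as a block, repeated quantile normalization, median centring of arrays, a filter on the dimmest 40% of genes, the mean of or each of a gene's probe sets, a trended robust variance, a fit on the compared arrays alone, a minimum change of 1.5-fold, each array left out in turn, an estimated correlation between genes, and fry. Bootstrap intervals over list members used 10000 resamples.

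The fit was tested on simulated data in which 200 genes were changed by 1.5-, 2- or 4-fold. In the simulation of knockdown in DMSO it called 94% of the 67 genes changed by 1.5-fold and 100% of those changed by 2- and 4-fold, with 12 false calls among 208. In that of the interaction it called 59.7% at 1.5-fold, 98.5% at 2-fold and 100% at 4-fold, with 15 false calls among 187. A shift of 0.5 given to the mitosis list was called by camera, and 0 of the 24 other lists were. The simulated noise was independent between genes, so the simulation could not show false list calls from genes that vary together. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.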

Results

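Genome-wide mRNA levels were measured on 8 arrays in COLO829, an established human melanoma cell line that carries an activating BRAF mutation. The cells had received either a short hairpin RNA against MITF, the lineage transcription factor of melanocytes, or a scrambled hairpin, and after 2 days of selection with puromycin they were treated for 24 h with 1 µM PLX4032 (vemurafenib, an inhibitor of mutant BRAF) or with its solvent DMSO. The 4 combinations of hairpin and treatment had 2 arrays each, A and B, and 18404 genes were tested. The design asks which genes depend on MITF, which respond to BRAF inhibition, and whether the response to the inhibitor differs when MITF is reduced. Changes below are on the log2 scale and are given ± SE from the limma fit over all 8 arrays (n = 2 arrays per group), and levels are given ± SD. The number of arrays limits the precision: the median SE of a change was 0.0939, and 0.133 for the interaction.

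The groups stood well apart from the spread between replicates. The Pearson correlation between the 2 arrays of a group lay between 0.99734 and 0.99844 across genes, and that between arrays of different groups between 0.9628 and 0.9844. The SD between replicates was 0.126 in scrambled DMSO cells, 0.109 in scrambled PLX4032 cells, 0.0935 in knockdown DMSO cells and 0.122 in knockdown PLX4032 cells. The first principal component, with 48.6% of the variance, parted the PLX4032 arrays from the DMSO arrays, and the second, with 37.3%, parted knockdown from scrambled arrays.

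MITF itself was lower in all 4 knockdown arrays than in the scrambled arrays of the same treatment. Its probe set, 8080938, read 10.45 ± 0.014 in scrambled DMSO cells (10.443 and 10.463) and 9.52 ± 0.069 in knockdown DMSO cells (9.568 and 9.4701), a 1.91-fold fall (log2 change -0.93 ± 0.080, limma adjusted p = 8.28e-06). Under PLX4032 it read 10.84 ± 0.055 in scrambled cells (10.879 and 10.801) and 10.08 ± 0.0060 in knockdown cells (10.072 and 10.08), a 1.7-fold fall (-0.76 ± 0.080, adjusted p = 3.02e-05). PLX4032 raised MITF by 0.39 ± 0.080 in scrambled cells (adjusted p = 0.00319) and by 0.56 ± 0.080 in knockdown cells (adjusted p = 0.000239). The difference between these rises, 0.17 ± 0.11, did not pass the threshold (adjusted p = 0.415). MITF in knockdown cells under PLX4032 stayed 1.3-fold below its level in scrambled DMSO cells (-0.38 ± 0.080, adjusted p = 0.00253).

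**Figure D1:**
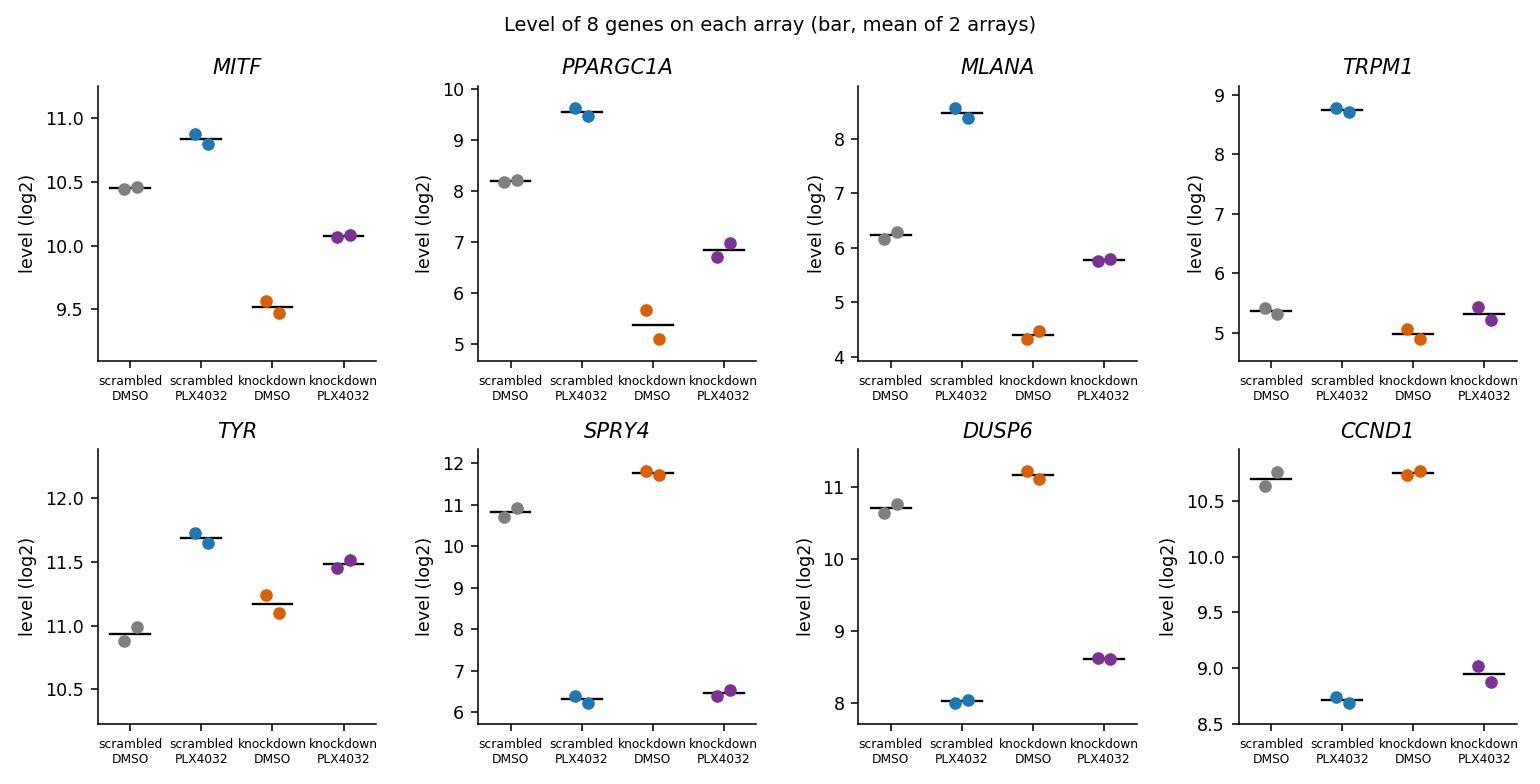
Log2 level of MITF, 4 genes tied to MITF (PPARGC1A, MLANA, TRPM1, TYR) and 3 outputs of BRAF signalling (SPRY4, DUSP6, CCND1) on each of the 8 arrays, by group (points are arrays, bars the mean of 2 arrays; each panel has its own vertical range). TRPM1 stood at 8.75 in scrambled PLX4032 cells and at 5.32 or 5.37 in knockdown PLX4032 and scrambled DMSO cells.

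Without the inhibitor, MITF knockdown lowered pigment and cell division genes and raised interferon-stimulated and invasion-associated genes. The largest rises were those of the cystatin gene CST1 (4.96 ± 0.27, 31.1-fold), the activin antagonist FST (4.55 ± 0.091, 23.4-fold), the interferon-inducible chemokine CXCL10 (4.39 ± 0.079) and XAF1 (4.05 ± 0.21), followed by SERPINB10 (4.01 ± 0.098), OAS2 (3.83 ± 0.27), CRLF2 (3.71 ± 0.14), ITIH6 (3.64 ± 0.11), IFIT1 (3.62 ± 0.32) and IFIT2 (3.59 ± 0.12). The largest falls were those of SPATS1 (-3.51 ± 0.11), the endopeptidase gene MME (-3.39 ± 0.18), GYG2 (-3.06 ± 0.086) and PPARGC1A, which encodes a coactivator of mitochondrial biogenesis (-2.81 ± 0.16, 7.03-fold lower). SEMA6A (-2.78 ± 0.12), STK32A (-2.65 ± 0.10), CA8 (-2.58 ± 0.12), TYRP1 (-2.55 ± 0.098), PLXNC1 (-2.54 ± 0.084) and CABLES1 (-2.51 ± 0.077) followed. Adjusted p for these 20 genes was at most 1.05e-05. Array probes for CST1 can read related cystatins.

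Pigment genes fell as a group. Of 21 measured pigmentation and melanosome genes, 2 rose and 14 fell (4 and 15 adjusted over the list alone), with a median log2 change of -0.68 (camera adjusted p = 3.15e-07, and adjusted p = 0.182 with an estimated correlation). The melanosomal enzyme gene TYRP1 (-2.55 ± 0.098), the vesicle trafficking gene LYST (-2.21 ± 0.081), the melanocyte antigen gene MLANA (-1.83 ± 0.095) and the melanosome transport gene RAB27A (-1.48 ± 0.15) changed most. Tyrosinase, TYR, read 0.23 ± 0.088 and did not pass the threshold (adjusted p = 0.0644). Of 20 other genes reported as MITF targets, 13 fell and 0 rose (17 and 0 adjusted over the list alone), with a median log2 change of -0.43 (camera adjusted p = 1.25e-07, and adjusted p = 0.168 with an estimated correlation). PPARGC1A, TRIM63 (-1.56 ± 0.11), STX7 (-1.26 ± 0.080) and RRAGD (-1.21 ± 0.086) led these. TRPM1 fell by little (-0.40 ± 0.099, adjusted p = 0.0108), and the call ended without knockdown DMSO replicate B or scrambled DMSO replicate A (log2 change between -0.35 and -0.31 in those fits). It stood at only 5.37 in scrambled DMSO cells, below the median gene (6.766), so a larger fall could have been hidden. Lineage regulators moved the other way on balance. Of 17 lineage and neural crest regulators, 9 rose and 3 fell (10 and 3 adjusted over the list alone), with a median log2 change of 0.25 (camera adjusted p = 0.0271, and adjusted p = 0.339 with an estimated correlation). The neural crest receptor gene NGFR (1.51 ± 0.077), RXRG (1.36 ± 0.077) and SOX2 (1.28 ± 0.11) rose, and ETS1 (-1.64 ± 0.079) fell.

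Cell division genes fell throughout. Of 25 mitosis genes, 25 fell and 0 rose (the same counts adjusted over the list alone), with a median log2 change of -0.90 (camera adjusted p = 5.05e-18, and adjusted p = 0.168 with an estimated correlation). Of 25 DNA replication genes, 25 fell and 0 rose (the same counts adjusted over the list alone), with a median log2 change of -0.77 (camera adjusted p = 1.1e-15, and adjusted p = 0.168 with an estimated correlation). The spindle checkpoint kinase gene BUB1B (-1.64 ± 0.12), BUB1 (-1.16 ± 0.12) and TTK (-1.14 ± 0.13) led the first list, and POLE2 (-1.55 ± 0.14), GINS1 (-1.19 ± 0.10) and ORC1 (-1.14 ± 0.12) the second.

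Interferon-stimulated genes rose together. Of 21 interferon response genes, 20 rose and 0 fell (21 and 0 adjusted over the list alone), with a median log2 change of 2.21 (camera adjusted p = 4.54e-19, and adjusted p = 0.182 with an estimated correlation). The antiviral genes OAS2 (3.83 ± 0.27), IFIT1 (3.62 ± 0.32), IFIT2 (3.59 ± 0.12) and IFI44L (3.45 ± 0.30) rose most. Of 11 antigen presentation genes, 10 rose and 0 fell (the same counts adjusted over the list alone), with a median log2 change of 0.64 (camera adjusted p = 5.03e-06, and adjusted p = 0.153 with an estimated correlation). The peptide transporter gene TAP1 (1.28 ± 0.12), the immunoproteasome gene PSMB9 (0.80 ± 0.088) and the peptidase gene ERAP1 (0.73 ± 0.079) led it. The 10 include HLA-DMA, whose probe sets gave opposite directions and which is left open, so 9 genes rose without it. Of 15 NF-kB and inflammatory genes, 10 rose and 1 fell (the same counts adjusted over the list alone), with a median log2 change of 0.50 (camera adjusted p = 3.7e-05, and adjusted p = 0.153 with an estimated correlation). The chemokine genes CXCL8 (2.70 ± 0.11) and CCL2 (1.14 ± 0.11), the cytokine gene IL24 (1.62 ± 0.20) and NFKB1 (1.07 ± 0.094) rose. Among 11 leukocyte markers 0 rose and 1 fell, with the same counts adjusted over the list alone and a median log2 change of 0.061 (camera adjusted p = 0.822).

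Of 24 genes of the invasive state of melanoma with low MITF, 14 rose and 2 fell (16 and 2 adjusted over the list alone), with a median log2 change of 0.46 (camera adjusted p = 5.58e-08, and adjusted p = 0.153 with an estimated correlation). The activin subunit gene INHBA (2.74 ± 0.11), the receptor tyrosine kinase gene AXL (2.09 ± 0.080), the matrix gene TNC (1.93 ± 0.082) and CCN2 (1.87 ± 0.11) rose most. Of 20 receptor tyrosine kinase and adaptor genes, 9 rose and 2 fell (the same counts adjusted over the list alone), with a median log2 change of 0.21 (camera adjusted p = 0.022, and adjusted p = 0.182 with an estimated correlation). AXL and MERTK (0.57 ± 0.081) rose, whereas GAB2 (-1.79 ± 0.098) and MET (-0.90 ± 0.092) fell, and 5 members rose without knockdown DMSO replicate A. Of 27 MAPK pathway output genes, 15 rose and 2 fell (the same counts adjusted over the list alone), with a median log2 change of 0.35 (camera adjusted p = 3.17e-05, and adjusted p = 0.199 with an estimated correlation). CXCL8, DUSP5 (1.86 ± 0.095), EGR1 (1.34 ± 0.14) and FOS (1.34 ± 0.11) rose.

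Metabolic lists fell by less. Of 33 oxidative phosphorylation genes, 15 fell and 0 rose (the same counts adjusted over the list alone), with a median log2 change of -0.23 (camera adjusted p = 3.17e-05, and adjusted p = 0.339 with an estimated correlation). Of 16 TCA cycle genes and mitochondrial regulators, 12 fell and 0 rose (the same counts adjusted over the list alone), with a median log2 change of -0.34 (camera adjusted p = 0.000153, and adjusted p = 0.199 with an estimated correlation). Besides PPARGC1A, the mitochondrial transcription factor gene TFAM (-0.59 ± 0.11) and citrate synthase, CS (-0.47 ± 0.083), fell. The lists for ribosome biogenesis (median -0.26, 1 rose and 9 fell (1 and 11 adjusted over the list alone)), sterol and fatty acid synthesis (-0.24, 7 fell and 0 rose (10 and 1 adjusted over the list alone)), glycolysis (-0.17, 1 rose and 8 fell (1 and 9 adjusted over the list alone)) and housekeeping genes (-0.23, 3 fell and 0 rose (5 and 0 adjusted over the list alone)) were also called down. Their adjusted p-values were 0.00264, 0.00341, 0.00469 and 0.0271, and with an estimated correlation the adjusted p-values were 0.387, 0.339, 0.41 and 0.428. These 4 calls ended when the dimmest 40% of genes were left out, and that of the housekeeping list ended under repeated quantile normalization too. The count of falls in the oxidative phosphorylation list dropped without scrambled DMSO replicate B. Those in the TCA cycle, ribosome biogenesis, sterol and housekeeping lists dropped without knockdown DMSO replicate B. A fit with 1 array in a group has less power, so these drops do not show that the changes came from those arrays. UQCRC2 (-0.39) and NDUFA9 (-0.39) each lost the call without 1 or the other of those arrays. Their changes were then -0.33 to -0.32 and -0.36 to -0.28.

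In all, 6114 of 18404 genes changed on knockdown in DMSO, of which 2655 rose and 3459 fell, and 1948 of them changed by at least 1.5-fold as well. Without knockdown DMSO replicate B the count was 3723.

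In scrambled cells, PLX4032 lowered outputs of MAPK signalling and cell division genes and raised pigment genes. The potassium channel gene KCNJ13 rose by 6.33 ± 0.10 (80.6-fold), ahead of ANGPTL7 (3.81 ± 0.12), BCAN (3.61 ± 0.11), the melanocyte channel gene TRPM1 (3.38 ± 0.099, 10.4-fold), RFTN2 (3.25 ± 0.10), LRRC39 (3.16 ± 0.17), ASPA (3.15 ± 0.10), the myelin gene MBP (3.06 ± 0.090), LGI3 (2.94 ± 0.087) and CDK15 (2.91 ± 0.18). The largest falls were those of MRGPRX4 (-4.93 ± 0.18), the signalling inhibitor gene SPRY4 (-4.50 ± 0.10, 22.7-fold), SYTL5 (-4.20 ± 0.094), the ETS factor gene ETV4 (-3.96 ± 0.089) and the cytokine gene LIF (-3.73 ± 0.093), and GRAMD1B (-3.54 ± 0.16), STC1 (-3.54 ± 0.12), LPL (-3.48 ± 0.084), SPATS1 (-3.08 ± 0.11) and CXCL8 (-3.04 ± 0.11) followed. Adjusted p was at most 6.02e-07 over these 20 genes. MRGPRX4 belongs to a receptor family with close relatives, which its probes can also read.

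Of 27 MAPK pathway output genes, 1 rose and 23 fell (1 and 24 adjusted over the list alone), with a median log2 change of -1.96 (camera adjusted p = 1.16e-20, and adjusted p = 0.158 with an estimated correlation). SPRY4, ETV4, LIF and CXCL8 led them, and the phosphatase gene DUSP6 (-2.68 ± 0.084) and the cyclin gene CCND1 (-1.98 ± 0.087) fell as well. Of 25 DNA replication genes, 25 fell and 0 rose (the same counts adjusted over the list alone), with a median log2 change of -1.12 (camera adjusted p = 8.26e-21, and adjusted p = 0.158 with an estimated correlation). Of 25 mitosis genes, 25 fell and 0 rose (the same counts adjusted over the list alone), with a median log2 change of -1.11 (camera adjusted p = 1.16e-20, and adjusted p = 0.158 with an estimated correlation). POLE2 (-1.83 ± 0.14), ORC1 (-1.75 ± 0.12), BUB1B (-1.53 ± 0.12) and CENPE (-1.49 ± 0.089) were among the largest falls. Of 17 ribosome biogenesis genes, 16 fell and 0 rose (17 and 0 adjusted over the list alone), with a median log2 change of -0.75 (camera adjusted p = 9.21e-12, and adjusted p = 0.158 with an estimated correlation). The RNA polymerase I subunit gene POLR1B (-1.52 ± 0.083) and the nucleolar genes NOLC1 (-1.34 ± 0.097) and DKC1 (-1.15 ± 0.11) fell most. Of 21 glycolysis genes, 1 rose and 17 fell (1 and 18 adjusted over the list alone), with a median log2 change of -0.49 (camera adjusted p = 6.01e-09, and adjusted p = 0.209 with an estimated correlation). The hexokinase gene HK2 (-1.97 ± 0.085), the glucose transporter gene SLC2A1 (-1.65 ± 0.092) and PFKFB4 (-1.62 ± 0.093) led that list.

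Of 21 pigmentation and melanosome genes, 16 rose and 0 fell (the same counts adjusted over the list alone), with a median log2 change of 0.75 (camera adjusted p = 4.13e-10, and adjusted p = 0.158 with an estimated correlation). MLANA (2.24 ± 0.095), TYRP1 (2.07 ± 0.098), MLPH (1.83 ± 0.13) and RAB27A (1.71 ± 0.15) rose most. Of 20 other reported MITF targets, 10 rose and 3 fell (11 and 3 adjusted over the list alone), with a median log2 change of 0.34 (camera adjusted p = 0.0211, and adjusted p = 0.481 with an estimated correlation). TRPM1, TRIM63 (2.24 ± 0.11), the receptor gene MET (1.36 ± 0.092) and PPARGC1A (1.36 ± 0.16, 2.56-fold, adjusted p = 6.79e-05) rose. Of 17 lineage regulators, 8 rose and 2 fell (the same counts adjusted over the list alone), with a median log2 change of 0.20 (camera adjusted p = 0.0137, and adjusted p = 0.358 with an estimated correlation). PAX3 (1.95 ± 0.089) and ETS1 (1.30 ± 0.079) rose, and LEF1 (-1.36 ± 0.084) fell. Of 25 lysosome and autophagy genes, 17 rose and 1 fell (18 and 1 adjusted over the list alone), with a median log2 change of 0.34 (camera adjusted p = 1.84e-05, and adjusted p = 0.406 with an estimated correlation). GABARAPL1 (0.99 ± 0.083), ARSA (0.74 ± 0.086) and HEXA (0.69 ± 0.080) rose, and NPC1 (-0.69 ± 0.077) fell, and 10 members rose without scrambled PLX4032 replicate A.

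Of 24 invasive-state genes, 4 rose and 13 fell (the same counts adjusted over the list alone), with a median log2 change of -0.37 (camera adjusted p = 0.00155, and adjusted p = 0.158 with an estimated correlation). NT5E (-2.44 ± 0.080), INHBA (-2.29 ± 0.11) and ZEB1 (-1.53 ± 0.095) fell, whereas JUN (2.29 ± 0.094) rose. Of 15 NF-kB and inflammatory genes, 2 rose and 6 fell (the same counts adjusted over the list alone), with a median log2 change of -0.095 (camera adjusted p = 0.0248, and adjusted p = 0.271 with an estimated correlation). CXCL8 and the NF-kB inhibitor gene TNFAIP3 (-2.66 ± 0.087) fell, NFKBIA (0.78 ± 0.091) rose, and the median was -0.1742 without scrambled DMSO replicate A. Of 9 housekeeping genes, 4 fell and 0 rose (the same counts adjusted over the list alone), with a median log2 change of -0.22 (camera adjusted p = 0.0299, and adjusted p = 0.53 with an estimated correlation). HPRT1 (-1.25 ± 0.11) and PGK1 (-0.47 ± 0.084) fell most, and without scrambled PLX4032 replicate B 2 members fell with a median of -0.1269. The last 2 list calls ended when the dimmest 40% of genes were left out, and the housekeeping call under repeated quantile normalization too. PLX4032 changed 6278 genes in scrambled cells, 3193 up and 3085 down, of which 2345 changed by at least 1.5-fold as well. The share that rose was 50.9%, and 45.6% with median centring of arrays.

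In MITF knockdown cells, PLX4032 again lowered MAPK outputs and cell division genes. ANGPTL7 (5.82 ± 0.12) and KCNJ13 (5.24 ± 0.10) rose most, followed by the prostaglandin dehydrogenase gene HPGD (3.97 ± 0.098), the serotonin receptor gene HTR2B (3.71 ± 0.11), ASPA (3.59 ± 0.10), TYRP1 (3.48 ± 0.098), CCDC146 (3.29 ± 0.096), the pro-apoptotic gene BMF (3.27 ± 0.088), DPYSL3 (3.21 ± 0.092) and OLFML2B (3.19 ± 0.096). The largest falls were MRGPRX4 (-6.11 ± 0.18), SPRY4 (-5.30 ± 0.10, 39.4-fold), ETV4 (-5.15 ± 0.089), the receptor gene APLNR (-4.68 ± 0.23) and GRAMD1B (-4.44 ± 0.16), with TM4SF1 (-4.33 ± 0.093), DCSTAMP (-4.23 ± 0.099), SERPIND1 (-4.21 ± 0.18), INHBA (-4.18 ± 0.11) and CRLF2 (-4.03 ± 0.14) next. Adjusted p for these 20 genes was at most 6.33e-08. PLX4032 changed 6206 genes in these cells, 3418 up and 2788 down, and 2644 of them by at least 1.5-fold as well. Median centring of arrays turned the majority, from 55.1% to 47.1% up.

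Of 27 MAPK pathway output genes, 2 rose and 23 fell (the same counts adjusted over the list alone), with a median log2 change of -1.70 (camera adjusted p = 1.43e-18, and adjusted p = 0.23 with an estimated correlation). ETV5 (-3.33 ± 0.085), LIF (-3.03 ± 0.093), DUSP6 (-2.55 ± 0.084) and CCND1 (-1.80 ± 0.087) fell. Of 25 DNA replication genes, 24 fell and 0 rose (25 and 0 adjusted over the list alone), with a median log2 change of -1.01 (camera adjusted p = 1.25e-19, and adjusted p = 0.23 with an estimated correlation). Of 25 mitosis genes, 24 fell and 0 rose (the same counts adjusted over the list alone), with a median log2 change of -0.74 (camera adjusted p = 5.41e-14, and adjusted p = 0.284 with an estimated correlation). The replication licensing gene CDC6 (-2.57 ± 0.092), MCM10 (-2.19 ± 0.10), CDK1 (-1.45 ± 0.18) and KIF11 (-1.17 ± 0.12) were among the largest falls. Of 17 ribosome biogenesis genes, 17 fell and 0 rose (the same counts adjusted over the list alone), with a median log2 change of -0.74 (camera adjusted p = 6.88e-13, and adjusted p = 0.23 with an estimated correlation). POLR1B (-1.52 ± 0.083) and DKC1 (-1.39 ± 0.11) fell most. Of 21 glycolysis genes, 1 rose and 19 fell (the same counts adjusted over the list alone), with a median log2 change of -0.67 (camera adjusted p = 6.07e-12, and adjusted p = 0.23 with an estimated correlation). HK2 (-2.47 ± 0.085), PFKFB4 (-2.06 ± 0.093) and PDK1 (-2.01 ± 0.081) fell. Of 16 sterol and fatty acid synthesis genes, 1 rose and 10 fell (1 and 11 adjusted over the list alone), with a median log2 change of -0.35 (camera adjusted p = 3.03e-05, and adjusted p = 0.32 with an estimated correlation). DHCR7 (-1.81 ± 0.094), fatty acid synthase, FASN (-1.32 ± 0.086), and SQLE (-1.25 ± 0.081) fell.

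Of 21 pigmentation and melanosome genes, 12 rose and 3 fell (13 and 3 adjusted over the list alone), with a median log2 change of 0.32 (camera adjusted p = 0.00585, and adjusted p = 0.539 with an estimated correlation). TYRP1 (3.48 ± 0.098), LYST (2.52 ± 0.081) and MLANA (1.38 ± 0.095) rose, and the melanosomal transporter gene SLC45A2 (-1.67 ± 0.11) fell. PPARGC1A rose by 1.46 ± 0.16 (adjusted p = 3.14e-05). Of 25 lysosome and autophagy genes, 16 rose and 1 fell (21 and 1 adjusted over the list alone), with a median log2 change of 0.30 (camera adjusted p = 0.000139, and adjusted p = 0.539 with an estimated correlation). Of 17 lineage regulators, 8 rose and 1 fell (9 and 2 adjusted over the list alone), with a median log2 change of 0.24 (camera adjusted p = 0.0293, and adjusted p = 0.539 with an estimated correlation). FOXD3 (2.66 ± 0.11), ETS1 (2.24 ± 0.079) and NGFR (1.95 ± 0.077) rose, and LEF1 (-2.05 ± 0.084) fell. Of 15 p53 target genes, 8 rose and 2 fell (10 and 2 adjusted over the list alone), with a median log2 change of 0.35 (camera adjusted p = 0.0229, and adjusted p = 0.632 with an estimated correlation). ZMAT3 (1.42 ± 0.099) and DDB2 (0.82 ± 0.081) rose, and GDF15 (-0.95 ± 0.095) fell. Of 21 interferon response genes, 8 fell and 0 rose (9 and 0 adjusted over the list alone), with a median log2 change of -0.37 (camera adjusted p = 0.000404, and adjusted p = 0.666 with an estimated correlation). RSAD2 (-1.83 ± 0.15), HERC5 (-1.80 ± 0.13) and OASL (-1.23 ± 0.093) fell, and the median of the list was -0.222 without knockdown PLX4032 replicate B. Of 33 oxidative phosphorylation genes, 10 fell and 0 rose (9 and 0 adjusted over the list alone), with a median log2 change of -0.11 (camera adjusted p = 0.0131, and adjusted p = 0.666 with an estimated correlation). COX7B (-0.62 ± 0.11) and NDUFV2 (-0.53 ± 0.085) fell, and 6 members fell without knockdown DMSO replicate A, while the median ran from -0.1876 without knockdown PLX4032 replicate B to -0.052 without A. The calls of the lineage, p53 and oxidative phosphorylation lists ended when the dimmest 40% of genes were left out, and those of the interferon and oxidative phosphorylation lists with fry (adjusted p = 0.0753 and 0.0532).

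**Figure D2:**
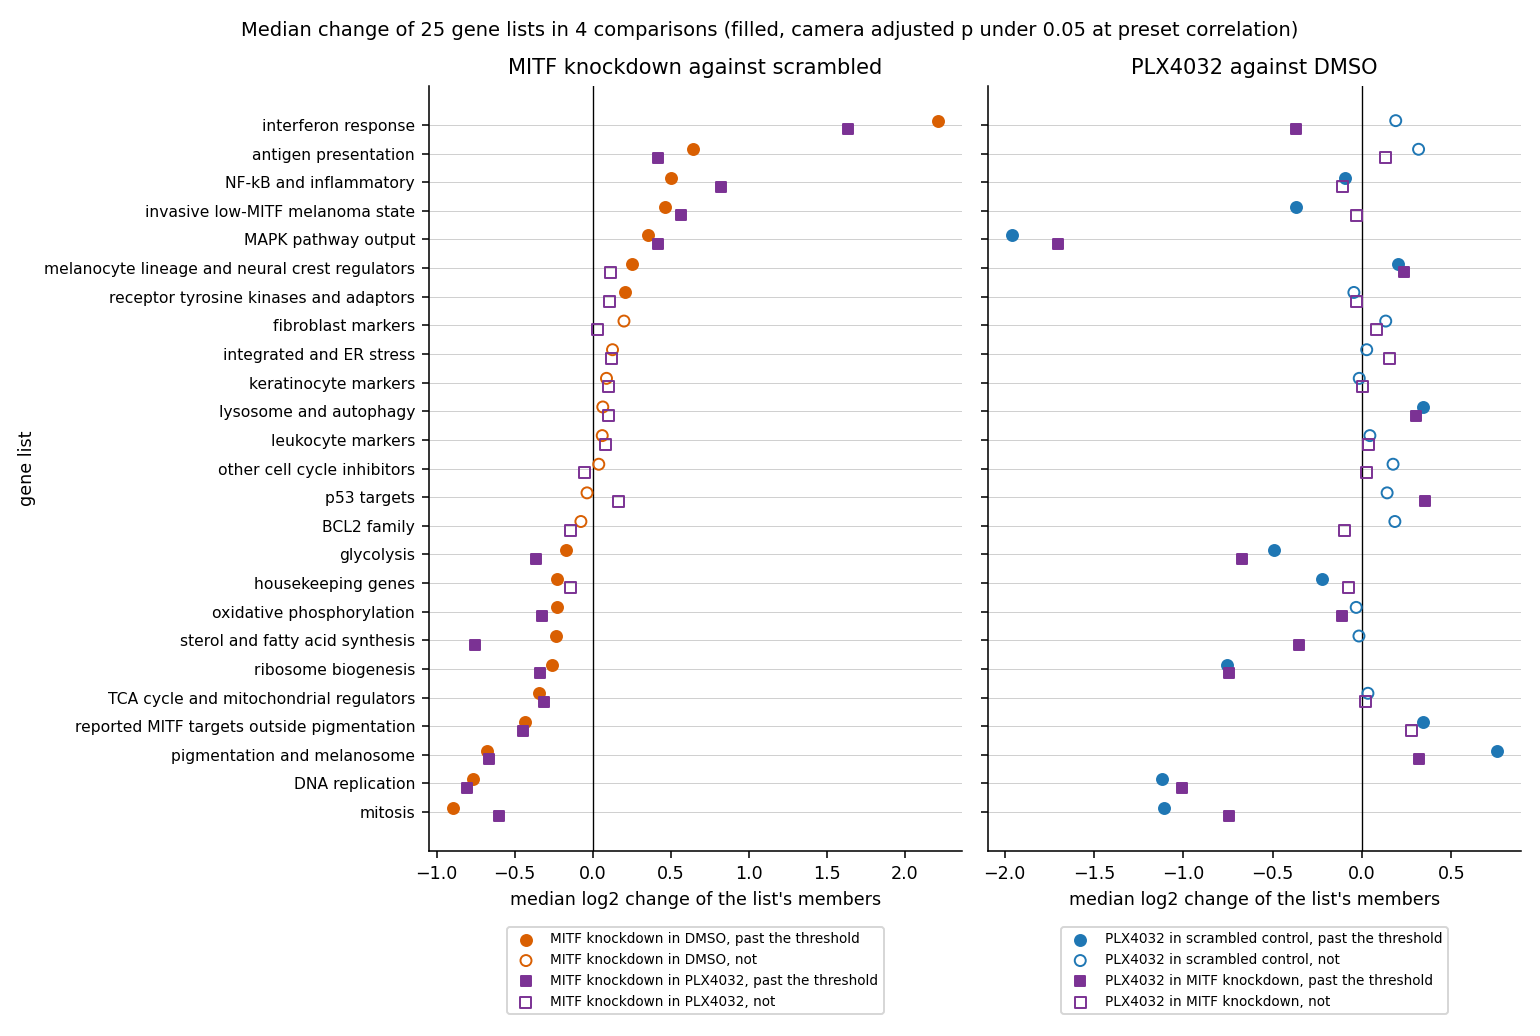
Median log2 change of the measured members of 25 gene lists in MITF knockdown against scrambled cells (left) and PLX4032 against DMSO (right), with filled symbols where camera passed the threshold at its preset correlation of 0.01 and open symbols elsewhere. Interferon response genes stood highest in both knockdown comparisons, and MAPK pathway output genes lowest in both PLX4032 comparisons.

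Among PLX4032-treated cells, those with MITF knockdown had lower pigment genes and higher interferon, inflammatory and invasion-associated genes. FST (4.37 ± 0.091) rose most, followed by SLITRK6 (4.25 ± 0.13), the integrin gene ITGA10 (4.05 ± 0.093), IL24 (3.81 ± 0.20), the proteoglycan gene VCAN (3.74 ± 0.11), NRXN3 (3.49 ± 0.079), LRP2 (3.46 ± 0.13), MOXD1 (3.43 ± 0.11), CCDC146 (3.42 ± 0.096) and IFIT2 (3.38 ± 0.12). The largest falls were those of AMBN (-3.56 ± 0.077), FRMD4B (-3.49 ± 0.11), TRPM1 (-3.43 ± 0.099, 10.8-fold), MET (-3.38 ± 0.092, 10.4-fold) and RAB27A (-3.10 ± 0.15), followed by MREG (-3.07 ± 0.082), DIPK1C (-3.04 ± 0.14), KCNAB2 (-2.96 ± 0.10), SERPINF1 (-2.95 ± 0.10) and PRDM7 (-2.88 ± 0.22). Adjusted p was at most 2.83e-06 for these 20 genes. PPARGC1A was 6.52-fold lower (-2.71 ± 0.16, adjusted p = 3.68e-07), and TYR, at -0.21 ± 0.088, did not pass the threshold (adjusted p = 0.11).

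Of 21 pigmentation and melanosome genes, 1 rose and 14 fell (1 and 16 adjusted over the list alone), with a median log2 change of -0.67 (camera adjusted p = 2.47e-11, and adjusted p = 0.14 with an estimated correlation). SLC45A2 (-2.76 ± 0.11) and MLANA (-2.70 ± 0.095) fell beside RAB27A and MREG. Of 20 other reported MITF targets, 2 rose and 12 fell (2 and 14 adjusted over the list alone), with a median log2 change of -0.44 (camera adjusted p = 1.16e-08, and adjusted p = 0.14 with an estimated correlation). TRIM63 (-2.54 ± 0.11) fell beside TRPM1, MET and PPARGC1A. Of 25 DNA replication genes, 22 fell and 0 rose (24 and 0 adjusted over the list alone), with a median log2 change of -0.80 (camera adjusted p = 3.04e-15, and adjusted p = 0.14 with an estimated correlation). Of 25 mitosis genes, 23 fell and 0 rose (24 and 0 adjusted over the list alone), with a median log2 change of -0.60 (camera adjusted p = 6.73e-12, and adjusted p = 0.211 with an estimated correlation). CDC6 (-1.80 ± 0.092), RRM2 (-1.63 ± 0.15), CDK1 (-0.99 ± 0.18) and AURKB (-0.98 ± 0.089) led those falls. Of 16 sterol and fatty acid synthesis genes, 14 fell and 0 rose (15 and 0 adjusted over the list alone), with a median log2 change of -0.75 (camera adjusted p = 3.26e-10, and adjusted p = 0.14 with an estimated correlation). HMGCS1 (-1.69 ± 0.097) and SQLE (-1.21 ± 0.081) fell most. Of 33 oxidative phosphorylation genes, 21 fell and 0 rose (28 and 0 adjusted over the list alone), with a median log2 change of -0.32 (camera adjusted p = 8.12e-10, and adjusted p = 0.211 with an estimated correlation). Of 16 TCA cycle genes and mitochondrial regulators, 10 fell and 0 rose (11 and 0 adjusted over the list alone), with a median log2 change of -0.31 (camera adjusted p = 0.000115, and adjusted p = 0.211 with an estimated correlation). COX7B (-1.35 ± 0.11), OGDH (-0.81 ± 0.090) and ESRRA (-0.72 ± 0.087) fell. Of 21 glycolysis genes, 1 rose and 13 fell (2 and 16 adjusted over the list alone), with a median log2 change of -0.36 (camera adjusted p = 1.6e-06, and adjusted p = 0.22 with an estimated correlation). Of 17 ribosome biogenesis genes, 12 fell and 0 rose (14 and 0 adjusted over the list alone), with a median log2 change of -0.34 (camera adjusted p = 5.79e-06, and adjusted p = 0.227 with an estimated correlation). PFKP (-1.32 ± 0.081), PDK1 (-1.01 ± 0.081) and DKC1 (-0.78 ± 0.11) fell. Without scrambled PLX4032 replicate A, 9 oxidative phosphorylation, 4 TCA cycle and 6 ribosome biogenesis genes fell.

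Of 21 interferon response genes, 19 rose and 1 fell (the same counts adjusted over the list alone), with a median log2 change of 1.64 (camera adjusted p = 4.73e-12, and adjusted p = 0.228 with an estimated correlation). IFI44L (3.37 ± 0.30), IFIT1 (2.79 ± 0.32) and IFIH1 (2.15 ± 0.15) rose beside IFIT2. The 2 scrambled PLX4032 arrays stood apart on this list, with a median SD of 0.3722 over its genes against 0.147 in knockdown PLX4032 cells, and the median change was 1.343 without replicate B and 1.962 without A. Of 15 NF-kB and inflammatory genes, 10 rose and 0 fell (the same counts adjusted over the list alone), with a median log2 change of 0.82 (camera adjusted p = 9.98e-08, and adjusted p = 0.123 with an estimated correlation). CXCL8 (3.06 ± 0.11), CCL2 (2.38 ± 0.11) and TNFAIP3 (1.30 ± 0.087) rose beside IL24. Of 11 antigen presentation genes, 7 rose and 0 fell (the same counts adjusted over the list alone), with a median log2 change of 0.42 (camera adjusted p = 0.00142, and adjusted p = 0.165 with an estimated correlation). ERAP1 (0.80 ± 0.079), TAP1 (0.78 ± 0.12) and B2M (0.57 ± 0.086) rose. Of 11 leukocyte markers, 1 rose and 2 fell (the same counts adjusted over the list alone) in this comparison. CD53 (1.49 ± 0.13) rose, and CORO1A (-0.85 ± 0.094) and CD79B (-0.51 ± 0.11) fell, the last not without scrambled PLX4032 replicate A (-0.33). Of 24 invasive-state genes, 13 rose and 2 fell (15 and 2 adjusted over the list alone), with a median log2 change of 0.57 (camera adjusted p = 3.53e-07, and adjusted p = 0.123 with an estimated correlation). NGFR (3.12 ± 0.077), TNC (3.06 ± 0.082), NT5E (2.48 ± 0.080) and AXL (2.19 ± 0.080) rose most. Of 27 MAPK pathway output genes, 14 rose and 6 fell (16 and 6 adjusted over the list alone), with a median log2 change of 0.42 (camera adjusted p = 0.00232, and adjusted p = 0.311 with an estimated correlation). EPHA2 (1.69 ± 0.088), FOS (1.67 ± 0.11) and LIF (1.56 ± 0.093) rose beside CXCL8. In all 5243 genes differed, 2480 higher and 2763 lower in knockdown cells, 1960 of them by at least 1.5-fold as well.

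Cells with both perturbations differed from scrambled DMSO cells in 8945 genes, 4979 higher and 3966 lower, 3718 of them by at least 1.5-fold as well. The majority direction depended on scaling, since 55.7% were higher here and 48.4% with median centring of arrays. ANGPTL7 (6.26 ± 0.12), KCNJ13 (4.84 ± 0.10), the matrix gene MATN2 (4.64 ± 0.092), CCDC146 (4.58 ± 0.096) and the transcription factor gene JUN (4.26 ± 0.094, 19.1-fold) rose most, followed by TCN1 (4.18 ± 0.085), RFTN2 (4.15 ± 0.10), SCRG1 (4.03 ± 0.13), MOXD1 (3.95 ± 0.11) and CMTM5 (3.85 ± 0.13). ETV4 fell by 5.16 on the log2 scale (35.8-fold), ahead of MRGPRX4 (-4.61 ± 0.18), SPRY4 (-4.35 ± 0.10), SPATS1 (-3.77 ± 0.11), GRAMD1B (-3.57 ± 0.16), SLC27A3 (-3.56 ± 0.11), the checkpoint gene CLSPN (-3.52 ± 0.12), POLE2 (-3.41 ± 0.14), ETV5 (-3.39 ± 0.085) and CDC6 (-3.30 ± 0.092). Adjusted p was at most 2.54e-08 for these 20 genes. DUSP6 (-2.09 ± 0.084), CCND1 (-1.75 ± 0.087), PPARGC1A (-1.35 ± 0.16) and MLANA (-0.46 ± 0.095) were lower, TYR (0.55 ± 0.088) was higher, and TRPM1, at -0.046 ± 0.099, did not pass the threshold (adjusted p = 0.726).

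Of 25 DNA replication genes, 25 fell and 0 rose (the same counts adjusted over the list alone), with a median log2 change of -2.06 (camera adjusted p = 1.81e-21, and adjusted p = 0.171 with an estimated correlation). Of 25 mitosis genes, 25 fell and 0 rose (the same counts adjusted over the list alone), with a median log2 change of -1.70 (camera adjusted p = 3.44e-20, and adjusted p = 0.171 with an estimated correlation). MCM10 (-3.14 ± 0.10), RRM2 (-2.87 ± 0.15), CDK1 (-2.34 ± 0.18) and BUB1B (-2.20 ± 0.12) fell by some of the widest margins. Of 17 ribosome biogenesis genes, 17 fell and 0 rose (the same counts adjusted over the list alone), with a median log2 change of -1.07 (camera adjusted p = 5.26e-12, and adjusted p = 0.171 with an estimated correlation). Of 21 glycolysis genes, 1 rose and 19 fell (the same counts adjusted over the list alone), with a median log2 change of -0.86 (camera adjusted p = 7.16e-12, and adjusted p = 0.171 with an estimated correlation). DKC1 (-1.93 ± 0.11), NOLC1 (-1.63 ± 0.097), PDK1 (-2.54 ± 0.081) and HK2 (-2.40 ± 0.085) fell. Of 27 MAPK pathway output genes, 4 rose and 20 fell (the same counts adjusted over the list alone), with a median log2 change of -0.98 (camera adjusted p = 4.44e-09, and adjusted p = 0.171 with an estimated correlation). Of 16 sterol and fatty acid synthesis genes, 12 fell and 0 rose (15 and 0 adjusted over the list alone), with a median log2 change of -0.65 (camera adjusted p = 7.79e-08, and adjusted p = 0.171 with an estimated correlation). SPRY1 (-2.53 ± 0.099), DHCR7 (-1.97 ± 0.094) and SQLE (-1.45 ± 0.081) fell. Of 21 interferon response genes, 19 rose and 0 fell (the same counts adjusted over the list alone), with a median log2 change of 1.65 (camera adjusted p = 5.99e-09, and adjusted p = 0.384 with an estimated correlation). IFIT2 (3.85 ± 0.12), IFIT1 (3.41 ± 0.32) and IFI44L (3.30 ± 0.30) rose. Of 17 lineage regulators, 13 rose and 1 fell (the same counts adjusted over the list alone), with a median log2 change of 0.56 (camera adjusted p = 0.000191, and adjusted p = 0.171 with an estimated correlation). NGFR (3.46 ± 0.077) and FOXD3 (3.20 ± 0.11) rose and LEF1 (-2.10 ± 0.084) fell. The 14 lists called also held oxidative phosphorylation (median -0.35), the TCA cycle list (-0.35), antigen presentation (0.69), lysosome and autophagy (0.37), reported MITF targets (-0.25) and housekeeping genes (-0.29). Their adjusted p-values with an estimated correlation were 0.302, 0.239, 0.171, 0.526, 0.384 and 0.43, and the last 2 calls ended when the dimmest 40% of genes were left out.

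**Figure D3:**
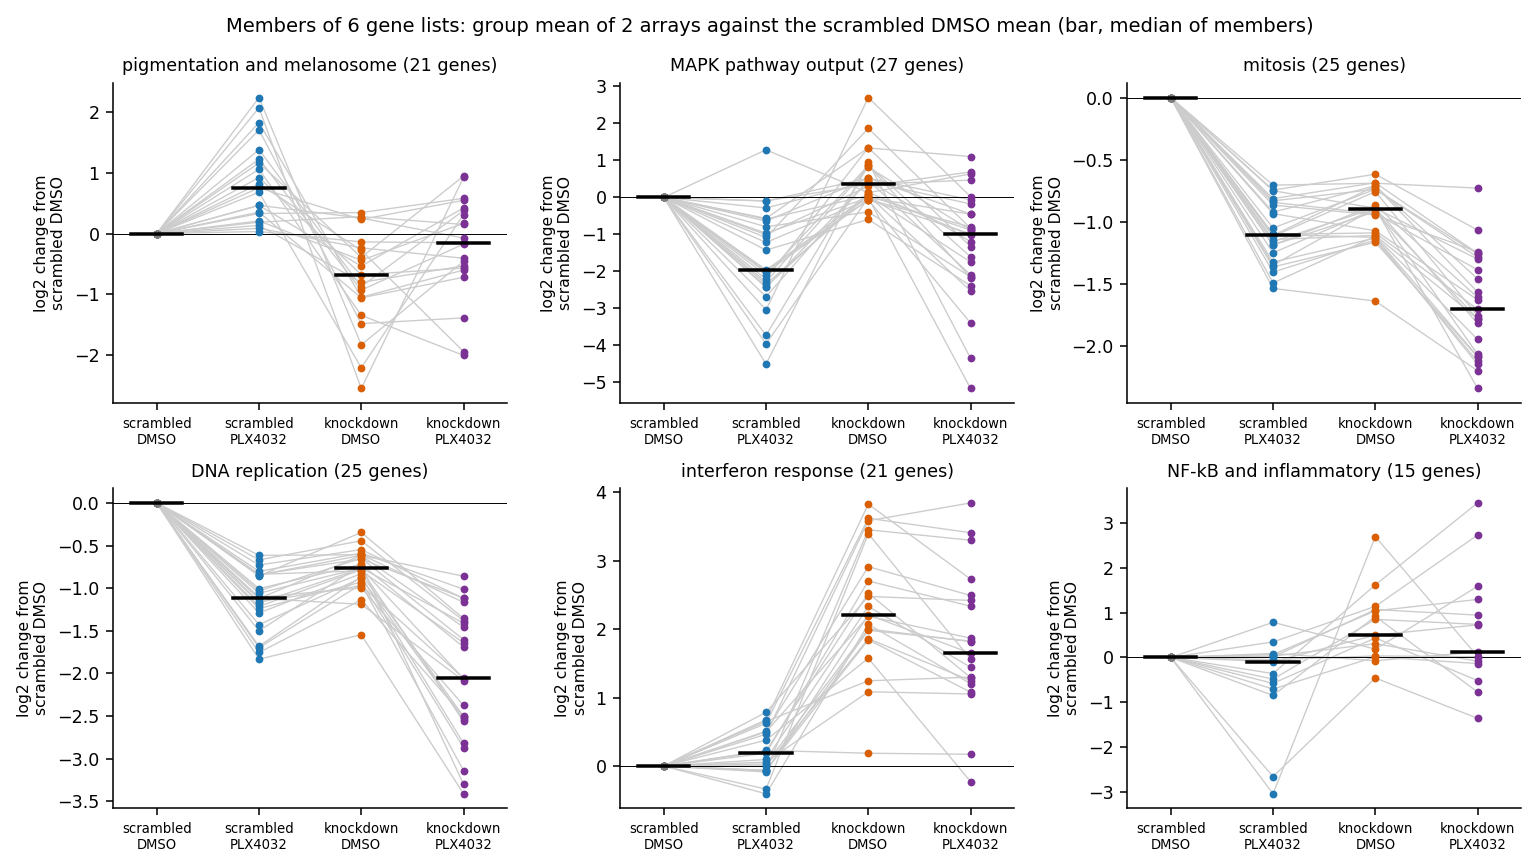
Members of 6 gene lists as the mean of 2 arrays in each group minus the mean in scrambled DMSO cells (log2). Points are genes, grey lines join the values of a gene, and bars are medians. The mitosis and DNA replication medians were lowest, at -1.70 and -2.06, in cells with both perturbations.

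Whether knockdown altered the response to PLX4032 was tested as the interaction, the PLX4032 change in knockdown cells minus that in scrambled cells. TRPM1 rose by 3.38 ± 0.099 in scrambled cells and changed by 0.35 ± 0.099 in knockdown cells, an interaction of -3.03 ± 0.14 (adjusted p = 1.11e-06). MET rose by 1.36 ± 0.092 in scrambled cells and fell in knockdown cells (-1.12 ± 0.092), an interaction of -2.48 ± 0.13 (adjusted p = 1.91e-06). The ubiquitin-like modifier gene UBD had the largest positive interaction (3.49 ± 0.28, adjusted p = 2.27e-05), with -0.56 ± 0.20 in scrambled and 2.93 ± 0.20 in knockdown cells. ITGA2 (2.89 ± 0.11), SYNE3 (2.88 ± 0.16), SPATS1 (2.82 ± 0.15), ABI3BP (2.65 ± 0.17), HTR2B (2.64 ± 0.16), LINC00341 (2.63 ± 0.14), PODXL (2.52 ± 0.11), DLX5 (2.44 ± 0.12) and SQOR (2.37 ± 0.24) followed. DCSTAMP (-3.96 ± 0.14) had the largest negative one, ahead of SERPINB10 (-3.74 ± 0.14), CRLF2 (-3.50 ± 0.19), CST1 (-2.80 ± 0.38), CCN2 (-2.78 ± 0.15), PLN (-2.53 ± 0.17), SOCS6 (-2.52 ± 0.12) and SLC45A2 (-2.49 ± 0.15). SPATS1, SERPINB10 and CRLF2 are not read as an altered response, because the arm that fell less began at a low level, with little room to fall. DCSTAMP and PLN also began below the median gene in scrambled cells. Some room was left there, since both read lower with both perturbations than in scrambled PLX4032 cells. A floor alone therefore does not account for their interactions. SPATS1 stood at 8.40, 5.33, 4.89 and 4.64 in scrambled DMSO, scrambled PLX4032, knockdown DMSO and knockdown PLX4032 cells, SERPINB10 at 3.45, 3.67, 7.46 and 3.94, CRLF2 at 3.84, 3.32, 7.55 and 3.53, DCSTAMP at 5.96, 5.69, 8.17 and 3.94, and PLN at 5.74, 5.87, 6.68 and 4.28. SPRY4 fell further in knockdown cells (interaction -0.80 ± 0.14, adjusted p = 0.00416), where its DMSO level was higher. It ended at 6.31 in scrambled and 6.46 in knockdown PLX4032 cells, so a floor shared by both arms is not excluded for this difference. PPARGC1A (0.11 ± 0.23, adjusted p = 0.834), DUSP6 (0.13 ± 0.12, 0.556) and CCND1 (0.18 ± 0.12, 0.423) showed no interaction past the threshold.

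At the preset correlation 8 of the 25 lists were called. Of 21 interferon response genes, 7 had a negative and 0 a positive interaction (12 and 0 adjusted over the list alone), with a median interaction of -0.61 (camera adjusted p = 1.79e-07, and adjusted p = 0.741 with an estimated correlation). HERC5 (-2.18 ± 0.18) and OAS2 (-1.77 ± 0.38) led, the latter not past the threshold with a trended robust variance. The size of this median rested on the scrambled PLX4032 arrays, which stood apart on the list: it was -0.3368 without replicate A and -0.8686 without B. By the rule for little room, 4 of the 21 members had it, 3 of them among the 7 called. The median interaction of the other members was -0.5564. Of 25 mitosis genes, 7 had a positive and 0 a negative interaction (14 and 0 adjusted over the list alone), with a median interaction of 0.36 (camera adjusted p = 1.41e-06, and adjusted p = 0.741 with an estimated correlation). BUB1B (0.97 ± 0.17) and KIF20A (0.66 ± 0.13) led these, and 3 members passed without knockdown DMSO replicate B. Of 16 sterol and fatty acid synthesis genes, 8 had a negative and 0 a positive interaction (9 and 0 adjusted over the list alone), with a median interaction of -0.48 (camera adjusted p = 1.87e-06, and adjusted p = 0.741 with an estimated correlation). STARD4 (-1.08 ± 0.16) and SQLE (-1.01 ± 0.11) had the largest negative interactions among them. Of 21 pigmentation and melanosome genes, 3 had a positive and 9 a negative interaction (4 and 9 adjusted over the list alone), with a median interaction of -0.26 (camera adjusted p = 0.00995, and adjusted p = 0.741 with an estimated correlation). SLC45A2 had a negative interaction, LYST (1.84 ± 0.11) a positive one and MLANA (-0.86 ± 0.14) a negative one, and the median was -0.1021 without knockdown PLX4032 replicate B. MLANA began at 4.40 in knockdown and 6.23 in scrambled DMSO cells, so compression of dim probe sets is not excluded for its smaller rise. Of 15 NF-kB and inflammatory genes, 5 had a positive and 1 a negative interaction (7 and 3 adjusted over the list alone), with a median interaction of 0.32 (camera adjusted p = 0.0242, and adjusted p = 0.741 with an estimated correlation). IL24 (2.19 ± 0.29) and TNFAIP3 (1.76 ± 0.12) were more positive in knockdown cells. The lists for glycolysis (median -0.19, 1 had a positive and 7 a negative interaction (1 and 8 adjusted over the list alone)), oxidative phosphorylation (-0.061, 4 had a negative and 0 a positive interaction (the same counts adjusted over the list alone)) and antigen presentation (-0.30, 2 had a negative and 0 a positive interaction (4 and 0 adjusted over the list alone)) were also called down (camera adjusted p = 0.00691, 0.0242 and 0.04997, and adjusted p = 0.741, 0.836 and 0.741 with an estimated correlation). Without knockdown DMSO replicate A, 2 glycolysis and 1 oxidative phosphorylation genes had a negative interaction past the threshold, and the antigen presentation median was -0.1388. The oxidative phosphorylation median was -0.1237 without knockdown PLX4032 replicate B and -0.03667 without scrambled PLX4032 replicate A. The 2 antigen presentation genes were HLA-DMA, whose direction differed between probe sets, and NLRC5, and each lost its call in 6 of the 8 fits that left out an array. The call of that list ended with the mean of a gene's probe sets. With fry the calls of the interferon (adjusted p = 0.127), mitosis (0.054), glycolysis (0.054), oxidative phosphorylation (0.194) and antigen presentation lists (0.0673) ended too.

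The interaction passed the threshold in 2176 genes, 1283 positive and 893 negative, 1389 of them with a size of at least 1.5-fold as well. The count was 1278 without knockdown DMSO replicate B, 1427 without knockdown DMSO replicate A and 1431 without scrambled PLX4032 replicate A. In 245 of the 2176, 120 negative and 125 positive, a gene fell under PLX4032 in 1 arm and neither fell as far nor rose in the other, where it began below the median gene.

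**Figure D4:**
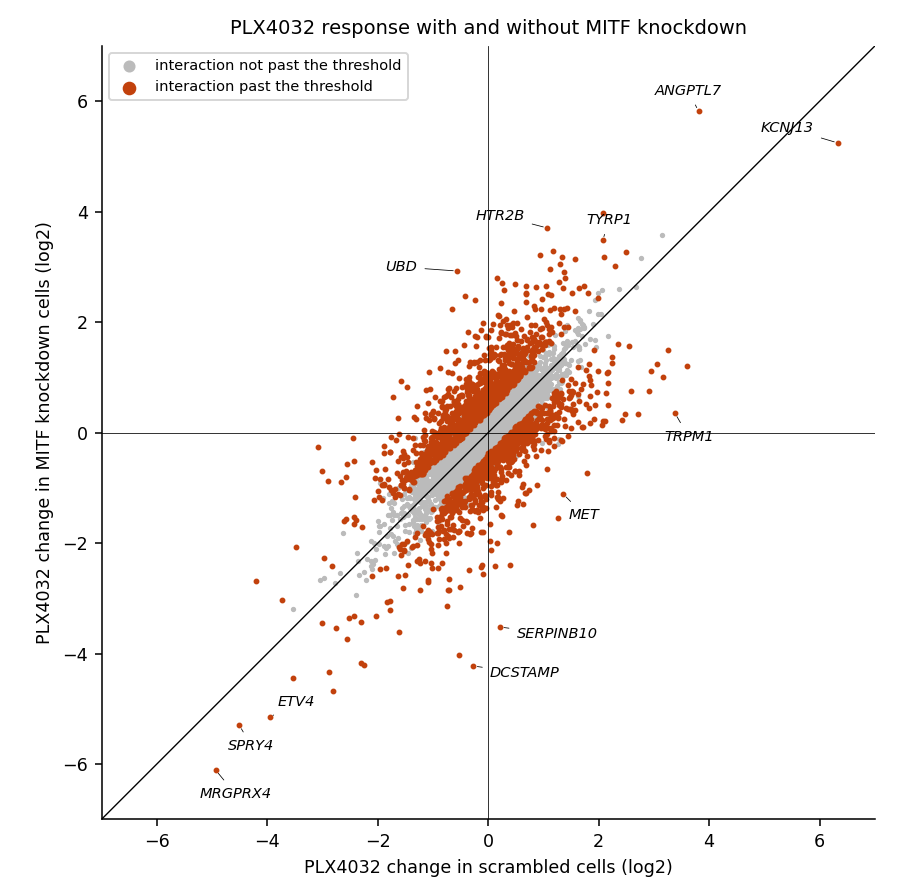
Log2 change under PLX4032 in scrambled cells (horizontal) and in MITF knockdown cells (vertical) for 18404 genes, with the line of equal change. Each point is a gene, and the 2176 genes whose interaction passed the threshold are coloured. TRPM1 and MET lie below the line, and UBD and HTR2B above it.

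Across genes, which are not independent replicates, the knockdown changes in DMSO and under PLX4032 correlated at r = 0.644 (Spearman rho 0.582), with no array in common. Of 3245 genes called in both, 3030 changed in the same direction and 215 in opposite directions. Both rose in 1243 genes, where independent lists would share 358, and both fell in 1787, where they would share 519. The PLX4032 changes in scrambled and knockdown cells correlated at r = 0.71 (rho 0.607), again with no array in common. They shared 4063 called genes, of which 3858 changed the same way and 205 the opposite way. Joint rises numbered 1914 against 593 for independent lists, and joint falls 1944 against 467. Knockdown in DMSO and PLX4032 in scrambled cells correlated at r = 0.144 (rho 0.31), but both were measured against the same 2 scrambled DMSO arrays. Simulated unchanged groups against shared controls gave r = 0.5 over 100 draws, with a covariance of 0.00528 against the observed 0.0281, a difference of 0.0228. The share of genes with the same sign was 66.2%, and 66.7% in the simulation. Sharing the controls alone sets the simulated share, so setting it beside the observed share tests nothing. Both rose in 858 genes (461 for independent lists) and both fell in 1498 (580), whereas 490 rose on knockdown and fell under PLX4032 (445) and 629 did the reverse (600). The simulation leaves out the effects and independent lists leave out the shared controls, so part of the excess may come from the shared controls. In a split chosen after the data were seen, each effect was set against its own scrambled DMSO array, without a test. With knockdown against replicate A and PLX4032 against B the correlation was 0.1041, the covariance 0.021 and the share with the same sign 61.1%, and with the arrays swapped they were 0.09486, 0.0194 and 57.4%. These 3 relations were the ones computed.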

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

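The 2 tests, of leukocyte RNA and of the hairpin construct, were chosen after the values they measure had been seen, whereas the other tests of the 3 patterns below were written once a pattern was known but before the value that decides them. The results below differ between groups by the interaction test, that is, the PLX4032 change in knockdown cells minus that in scrambled cells, or come from probe sets outside the gene table.

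The first pattern is the higher level of interferon response genes in both knockdown groups, with a median change of 2.21 in DMSO and 1.64 under PLX4032. A single aberrant array is argued against: with any 1 array left out the median stayed between 2.098 and 2.372 in DMSO, and between 1.343 (without scrambled PLX4032 replicate B) and 1.962 (without replicate A) under PLX4032. RNA from leukocytes is argued against as well, since the higher of the 2 median changes of 11 leukocyte markers was 0.08275 and at most 1 marker rose in either arm. A response to the hairpin construct rather than to the MITF level cannot be told apart, because the labels name a hairpin against MITF and no second one: with the hairpin held constant, PLX4032 raised MITF while the list's median changed by -0.3681 in knockdown cells (-0.5099 and -0.222 without knockdown PLX4032 replicate A and B) and by 0.1882 in scrambled cells (-0.08509 and 0.4553 without scrambled PLX4032 replicate A and B). A repression of interferon genes by MITF stays open beside it, untested.

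The second pattern is that mitosis genes fell less under PLX4032 in knockdown cells (median interaction 0.3618), in which they started lower. For a background floor of the array, the 22 of 25 members above the median level of all genes, 6.815, in cells with both perturbations were taken. Their median interaction was 0.3505 (95% bootstrap interval over members 0.2616 to 0.4423), so the pattern did not rest on members below that level. That interval treats members as independent and leaves out the spread between arrays. The members were chosen by their level in a group that enters the interaction, which favours positive values. Signal over background was not measured either, so the test cannot exclude a floor. A single array did not carry the pattern, as the median of the list stayed between 0.3079 and 0.4234 with any 1 array left out. The call of the list was lost with an estimated correlation (adjusted p = 0.741), as was every list call. The DNA replication list was not called (median interaction -0.0071, camera adjusted p = 0.637), and no biological explanation was tested.

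The third pattern is that pigmentation genes rose less at the median under PLX4032 in knockdown cells (median interaction -0.2581). Only part of the list did so: 9 of 21 members had a negative interaction past the threshold and 3 a positive one, such as LYST (1.84). The call was lost with an estimated correlation (adjusted p = 0.741), as was every list call. A single aberrant array cannot be excluded: without knockdown PLX4032 replicate B the median was -0.1021, and without replicate A of that group it was -0.3552, with an SD of 0.07779 over the 8 fits. Compression of bright probe sets cannot be excluded either, since the 13 of 21 members under 11 in every group had a median of -0.2581 with a 95% bootstrap interval of -1.381 to -0.01371. Compression of dim probe sets was not tested, and MLANA, for 1, read 4.40 in knockdown DMSO cells. Dependence of the induced pigment genes on MITF stays open.

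The other results are given as values. The interaction passed the threshold in 2176 genes. Median interactions of the other lists called were -0.6134 for interferon response (-0.8686 to -0.3368 with 1 array left out), -0.4761 for sterol and fatty acid synthesis, -0.1904 for glycolysis, 0.3233 for NF-kB and inflammatory genes, -0.3039 for antigen presentation and -0.06078 for oxidative phosphorylation, and none was called with an estimated correlation (adjusted p = 0.741 to 0.836). The positive interactions were UBD (3.49), ITGA2 (2.89), SYNE3 (2.88), SPATS1 (2.82), ABI3BP (2.65), HTR2B (2.64), LINC00341 (2.63), PODXL (2.52), DLX5 (2.44), SQOR (2.37), IL24 (2.19), LYST (1.84), TNFAIP3 (1.76), BUB1B (0.97), KIF20A (0.66) and SLC2A3 (0.63). The negative ones were DCSTAMP (-3.96), SERPINB10 (-3.74), CRLF2 (-3.50), TRPM1 (-3.03), CST1 (-2.80), CCN2 (-2.78), PLN (-2.53), SOCS6 (-2.52), SLC45A2 (-2.49), MET (-2.48), HERC5 (-2.18), OAS2 (-1.77), STARD4 (-1.08), SQLE (-1.01), COX7B (-0.94), MLANA (-0.86), SPRY4 (-0.80), PFKFB3 (-0.61), NDUFA1 (-0.51), NLRC5 (-0.50) and TYR (-0.44). The direction of HLA-DMA (-0.53) is open, since it was 0.2226 with the mean of its probe sets and 0.9738 with another probe set. SPRY4 ended at 6.31 in scrambled and 6.46 in knockdown PLX4032 cells, and a shared floor is not excluded for it. SPATS1, SERPINB10, CRLF2 and NLRC5 began below the median gene in the arm that fell less, so a floor is not excluded for them. DCSTAMP and PLN did so too, but in scrambled PLX4032 cells they stood at 5.69 and 5.87. That was above the 3.94 and 4.28 read with both perturbations, so a floor alone does not account for their interactions.

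The calls of 5 genes were lost in several of the fits that left out an array, so they were marginal rather than due to any one array. TYR ended in 7 of the 8 fits that left out an array, all but the one without scrambled DMSO replicate B (-0.51 to -0.37). HLA-DMA ended in 6 (-0.56 to -0.41), all but those without scrambled DMSO replicate B or scrambled PLX4032 replicate B. NLRC5 ended in 6 (-0.55 to -0.41), all but those without scrambled DMSO replicate A or knockdown PLX4032 replicate A. SLC2A3 ended without replicate B of knockdown DMSO, of knockdown PLX4032 or of scrambled DMSO, or without scrambled PLX4032 replicate A (0.51 to 0.58). NDUFA1 ended without either knockdown DMSO array or without scrambled PLX4032 replicate B (-0.53 to -0.45). Outside the gene table, cells with both perturbations differed from scrambled DMSO cells in 524 of the 1388 probe sets with several symbols and in 1551 of the 11775 not listed.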

How the results depend on the processing

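MITF's change kept its direction throughout. It lost its call only when a change of at least 1.5-fold was asked as well, for PLX4032 in scrambled cells (0.3867), PLX4032 in knockdown cells (0.5567) and both perturbations (-0.3772). Counts of changed genes stayed within 1.5 times under each alternative except a minimum change of 1.5-fold and some fits without 1 array. The first, which by construction asks for more, gave 1948 genes for knockdown in DMSO, 2345 for PLX4032 in scrambled cells, 2644 for PLX4032 in knockdown cells, 1960 for knockdown in PLX4032, 3718 for both perturbations and 1389 for the interaction. Leaving out 1 array in turn, where the lone array of a group is assumed to vary like the other groups, gave 3723 (without knockdown DMSO replicate B) to 6377 genes for knockdown in DMSO and 1278 (without the same array) to 2132 for the interaction. Same-lettered arrays of scrambled DMSO and knockdown PLX4032 cells deviated together in part, with a correlation of 0.329 between their A minus B differences across genes. For the other pairs of groups the correlations were -0.078, -0.0583, -0.0203, -0.00653 and -0.094. With the letter as a block the counts were 6146, 6295, 6202, 5279, 9031 and 2176 in the order above. The share of changed genes that rose moved by under 10 percentage points under either scaling, though with median centring it crossed 50% in 3 contrasts: from 50.9% to 45.6% for PLX4032 in scrambled cells, from 55.1% to 47.1% for PLX4032 in knockdown cells and from 55.7% to 48.4% for both perturbations. No scaling moved the median of all genes by over 0.1. The correlation of knockdown changes was 0.6868 without the dimmest 40% of genes and 0.582 as Spearman's rho, that of PLX4032 changes 0.7529 and 0.607, and that of knockdown in DMSO with PLX4032 in scrambled cells 0.1051, 0.3096 and, after repeated quantile normalization, 0.1052. With separate controls, chosen after the data were seen, the last was 0.1041 and 0.09486. The cause was not tested. Of 610 named gene results, 484 kept their call, and where called their direction, everywhere, and 537 did with the minimum change set aside. Of 9669 values under alternatives for them, 302 lost the call (108 for a change under 1.5-fold), 13 gained one and 8 reversed. Direction was compared only where the main fit or the alternative called the gene. A value called in neither counts as kept even if its sign changed. HLA-DMA reversed with the mean of its probe sets and with another of its probe sets alone, to -0.128 and -0.971 for knockdown in DMSO, -0.3625 and -1.384 for PLX4032 in scrambled cells, and 0.2226 and 0.9738 for the interaction. NPM1 read 0.0584 for knockdown in DMSO with another probe set, and TAP2 0.3134 for PLX4032 in knockdown cells with another probe set. The BCL2 family under PLX4032 in knockdown cells had a median of -0.09737, and fry called it up (adjusted p = 0.0182). Its mean was 0.029. Signal over background was not measured, which limits what dim genes can show.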

Other observations

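Several lists not described above, or not in every comparison, held strong single changes without a call as a group. In the BCL2 family, regulators of apoptosis, the pro-apoptotic gene BMF rose under PLX4032 by 2.49 ± 0.088 in scrambled cells and by 3.27 ± 0.088 in knockdown cells, and the pro-apoptotic gene PMAIP1 fell by 1.89 and 2.06. BCL2A1, an anti-apoptotic gene also reported as an MITF target, rose under PLX4032 in scrambled cells (0.88 ± 0.093) and fell in knockdown cells (-0.95 ± 0.093). Of the 15 members, 4 rose and 2 fell (the same counts adjusted over the list alone), median 0.18, camera adjusted p = 0.446 in scrambled cells, and 4 rose and 4 fell (5 and 5 adjusted over the list alone), median -0.097, camera adjusted p = 0.643 in knockdown cells, with 2 rising without scrambled PLX4032 replicate A in the first case and 2 without knockdown DMSO replicate B in the second. Among 15 p53 targets on knockdown in DMSO, 2 rose and 5 fell (the same counts adjusted over the list alone), median -0.037, camera adjusted p = 0.58, and 2 fell without knockdown DMSO replicate B. The rise of BBC3 in that comparison was not called without knockdown DMSO replicate B or without scrambled DMSO replicate B (0.30 in each fit). Among 8 other cell cycle inhibitors under PLX4032 in scrambled cells, 3 rose and 3 fell (4 and 3 adjusted over the list alone), median 0.17, camera adjusted p = 0.921: CDKN2B (-1.50 ± 0.082) fell, and CCNG2 (0.99 ± 0.093) and CDKN1B (0.77 ± 0.077) rose.

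Stress genes went both ways. Of 18 genes of the integrated and ER stress list under PLX4032 in scrambled cells, 5 rose and 5 fell (the same counts adjusted over the list alone), median 0.026, camera adjusted p = 0.811: the cystine transporter gene SLC7A11 (-1.65 ± 0.15) fell, and DNAJB9 (0.84 ± 0.12), DDIT3 (0.72 ± 0.083) and SESN2 (0.63 ± 0.12) rose. On knockdown in DMSO the serine synthesis genes PSAT1 (-1.11 ± 0.089) and PHGDH (-0.66 ± 0.081) of that list fell. Lysosome and autophagy genes on knockdown in DMSO were not called as a group, and 4 rose and 4 fell (5 and 5 adjusted over the list alone), median 0.064, camera adjusted p = 0.698, with WIPI1 (0.75 ± 0.078) up and ATP6V1B2 (-0.62 ± 0.087) down, and 2 rose without knockdown DMSO replicate A. Interferon response genes under PLX4032 in scrambled cells were not called either, and 5 rose and 0 fell (4 and 0 adjusted over the list alone), median 0.19, camera adjusted p = 0.246. Without scrambled PLX4032 replicate A 1 of them rose, and the 2 arrays of that group stood apart on this list (SD 1.00 for IFIT1, 0.87 for IFI44L and 0.77 for OAS2). For fibroblast markers on knockdown in DMSO, 2 rose and 2 fell (the same counts adjusted over the list alone), median 0.20, camera adjusted p = 0.698, and FAP (-0.84 ± 0.081) fell. The rise of PDGFRA was not called without knockdown DMSO replicate A or without either scrambled DMSO array (0.17 to 0.32 in those fits). For keratinocyte markers, 0 passed the threshold (the same counts adjusted over the list alone), median 0.088, camera adjusted p = 0.542, and SFN read 0.27 ± 0.10.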
